A study of Mus musculus with 4 samples.

How the data were processed

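RNA was measured in 4 cultures of palatal mesenchymal cells, the connective tissue cells of the developing secondary palate, which the labels describe as primary cultures from outbred wild-type mouse embryos at embryonic day 14. Per the labels' protocols, 1 culture was left untreated, 1 received TGF-beta2 for 120 minutes, and the remaining 2 were exposed for 60 minutes to a kinase inhibitor and then to TGF-beta2 for 120 minutes. The inhibitors were SB431542, which acts on the TGF-beta type I receptor kinase, and 5Z-7-oxozeaenol, which acts on the Tak1 kinase. Inhibitor doses were not given in the sources used here. Per the labels' protocols, 500 ng of total RNA per culture was amplified, biotin-labelled and hybridised to Affymetrix 3′ expression arrays, with 1 array per culture.

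The deposited values are intensities on a linear scale, with 1 value per array for each of 45101 probe sets. GCOS, the Affymetrix array software, is named in the submitters' processing notes. Its version, its summary algorithm and its settings are not given in the sources used here. The deposited intensities had a mean of 500.0 on every array once the lowest and highest 2% of probe sets were set aside, so the arrays had been brought to a common level before deposit. This kind of scaling assumes that the average transcript is equally abundant in all cultures. It leaves differences between arrays that depend on brightness, which the scaling alternatives addressed. Signals carry no unit beyond this common level, and levels of different probe sets were not set against each other.

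From these values, 64 control probe sets were left out. For the remaining 45037 probe sets, the platform annotation gave 1 gene symbol for 34945, several for 932 and none for 9160, and gene results use those with 1 symbol. The rest are reported only as counts, and a probe set with no listed gene is unnamed here. The table paired probe sets with symbols of 18193 genes, and no coordinates were used. Intensities were converted to log2(value + 21.7), where the pseudocount is the 25th percentile of all values. A probe set was kept when its mean over the 4 arrays reached the median of all non-control probe sets, a linear signal of about 66.1. Of the 20064 kept probe sets with 1 symbol, the brightest of each gene stood for it, which left 11744 genes, of which 5121 had at least 2 kept probe sets. Folds are on the log2(value + pseudocount) scale and understate the difference for dim genes.

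Each group held 1 array, so no spread between replicates could be estimated, no test was run and no p-value is given. The number of arrays limits the precision of every value. Genes were instead counted by a rule of size, at least 2-fold higher or lower between 2 arrays. Comparisons were TGF-beta2 over untreated, each inhibitor with TGF-beta2 over TGF-beta2 alone, the inhibitors against each other, and each inhibitor with TGF-beta2 over untreated. For a gene at least 2-fold higher or lower with TGF-beta2, its position with an inhibitor was the inhibitor array's difference from untreated divided by that of the TGF-beta2 array, on the log2 scale. A position of 0 is the untreated level and 1 the level with TGF-beta2 alone. To show what noise alone gives, 100 sets of 4 unchanged arrays were simulated, with noise by brightness taken from the untreated and TGF-beta2 arrays, the most alike pair. Part of that pair's difference is the response itself, so the simulated noise is not purely technical. It was drawn from a normal distribution with a robust spread. Single readings far off the rest are rare in it, so the simulated counts may be too low for real arrays. Intervals of median positions come from resampling the genes, and those of simulated positions from resampling the simulated genes. Genes share the same arrays and can vary together, so these intervals may be too narrow and do not measure spread between cultures.

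For gene lists the median log2 change is given with the range that held 95% of 10000 random lists of equal size, matched on mean expression over 20 bins. These ranges describe the arrays and are not tests between conditions. The 24 lists covered signalling targets, cell state and stress, palate regulators and markers of other cell types, and were fixed before the data were examined. A further list of epithelial genes in 2 classes was written after the data had been seen. Named genes followed a rule fixed before the data were examined. It took, per comparison, the 15 largest increases and 10 largest decreases of at least 2-fold whose kept probe sets all differed in the same direction, list members at least 2-fold apart, up to 4 examples per list, level controls, and the 10 genes responsive to TGF-beta2 with the largest difference between inhibitors. Genes outside this rule are marked where they appear.

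The counting and list steps were tested on simulated data for TGF-beta2 over untreated with 11744 genes, 200 of them altered. The 2-fold rule recovered 100.0% of genes altered 4-fold, 56.0% of those altered 2-fold and 3.0% of those altered 1.5-fold, with 12 to 16 unaltered genes also counted. Of 400 unaltered lists of 25 genes, 4.0% fell outside their 95% range. These lists were drawn at random with independent noise, so this does not cover lists of genes that vary together, for which the range may be too narrow.

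Alternatives fixed before the data were examined were pseudocounts at the 10th percentile (5.8) and at the median (69.7), no filter, a stricter filter at percentile 66.7 (a linear signal of about 206.6), quantile normalization, median centring, cyclic loess, the mean of a gene's probe sets, and leaving out probe sets whose names end in _x_at or _s_at. Added after the data had been seen were leaving out epithelial genes (that list and all other keratin, small proline-rich and late cornified envelope genes), leaving out genes that differed alike from untreated on all 3 stimulated arrays, and counting only genes whose probe sets shared a direction. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for quantile and cyclic loess scaling.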

Results

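Transcript levels were measured on 4 arrays of RNA from cultured mouse palatal mesenchymal cells: untreated, with TGF-beta2, with SB431542 and TGF-beta2, and with 5Z-7-oxozeaenol (oxozeaenol below) and TGF-beta2. TGF-beta2 is a growth factor that signals through the type I receptor kinase, which SB431542 blocks, to Smad transcription factors. The same ligand also activates Tak1, a kinase upstream of MAP kinases and NF-kappaB, which oxozeaenol inhibits. The design asks which transcripts respond to TGF-beta2 and which of these responses depend on each kinase. There were no replicates, so the differences below are between single arrays and have no replicate check.

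The 4 arrays were close in signal distribution, with medians of 66.3 (untreated), 68.2 (TGF-beta2), 72.7 (SB431542) and 71.6 (oxozeaenol). Pearson correlations between pairs of arrays, taken across probe sets, which are not independent replicates, lay between 0.975 and 0.982. Transcripts of Map3k7, which encodes Tak1, had signals of 480 (untreated), 551 (TGF-beta2), 539 (SB431542) and 575 (oxozeaenol). Tgfbr1, the type I receptor, stood at 3562 (untreated), 4881 (TGF-beta2), 3147 (SB431542) and 2893 (oxozeaenol). None of the 20 measured TGF-beta pathway components differed by 2-fold in any comparison. All 10 measured housekeeping genes were within 2-fold between any 2 arrays. Their median log2 change with TGF-beta2 was 0.05, and it was slightly below 0 under quantile normalization. Of 12 macrophage and blood markers, 8 were measured past the filter. Lyz2, which encodes lysozyme, read 15113 in the untreated culture and Csf1r, the receptor for macrophage colony-stimulating factor, read 8693. Of 12 genes in each list of endothelial and skeletal muscle markers, 4 were measured past the filter.

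The first comparison asks what differs 120 minutes after TGF-beta2. Fgf21, a metabolic hormone of the fibroblast growth factor family, was 8.1-fold higher, from a signal of 111 to 1056. Egr2, a zinc finger transcription factor, was 6.57-fold higher, and the cytokines Lif (4.59-fold), Il11 (4.03-fold) and Il6 (3.16-fold) were higher too. Rasl11b, a Ras-like GTPase gene, was 5.14-fold higher and Wnt9a, a Wnt ligand, 3.64-fold. Of 11744 genes, 79 were at least 2-fold higher and 43 at least 2-fold lower, against a median of 6 in each direction in simulated unchanged arrays. The simulation holds few single readings far off the rest, so 6 may be too low.

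Of 37 measured TGF-beta/Smad targets, 6 were at least 2-fold higher, 1 was lower and 30 lay within 2-fold, with a median log2 change of 0.17 (95% of random lists −0.09 to 0.06). Besides Lif and Il11, the higher ones were the transcription factor genes Bhlhe40 (1.41) and Junb (1.34), the sphingosine kinase gene Sphk1 (1.26) and the EGF receptor ligand gene Hbegf (1.18), all as log2 changes. Smad7 and Skil, negative regulators induced by Smads, had log2 changes of 0.35 and 0.73, below the 2-fold rule. Snai2, a repressor tied to mesenchymal identity, was the lower one at −1.02. Of 24 immediate early genes, 4 were at least 2-fold higher and none lower, among them Egr1, from 4390 to 10257 (median 0.27, random −0.12 to 0.06). Of 15 MAPK feedback genes, the phosphatase genes Dusp5 (1.58) and Dusp4 (1.00) were higher and 13 lay within 2-fold (median 0.33). Of 26 extracellular matrix genes, Has2, a hyaluronan synthase, was higher by 1.17 and 25 were within 2-fold. Vegfa, the vascular growth factor, was higher by 1.37, and the Wnt ligand Wnt11 by 1.17.

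Among genes lower with TGF-beta2, the chemokine Ccl3 was 5.48-fold lower, from 2646 to 466. Irs1, an adaptor of insulin signalling, was 3.1-fold lower and Ahr, the aryl hydrocarbon receptor, 2.85-fold lower. Dus2, Nxpe3, Ifit1bl1, Cdh3, Mm2pr, Col4a3 and Slitrk6 were also among the 10 largest decreases. Their signals with TGF-beta2 alone lay under the filter level, so the size of their decreases depends on the pseudocount. The 24 measured palatal mesenchyme regulators had a median log2 change of −0.15 (random −0.13 to 0.07). Of these, Osr1 (−1.39) and Alx1 (−1.23), both developmental transcription factors, were at least 2-fold lower and 22 were within 2-fold, and the 2 probe sets of Alx1 differed in direction. Of 11 BMP/Id targets, Id4 (−1.38) and Hey1 (−1.03) were lower and 9 were within 2-fold, with a median of −0.35 (random −0.14 to 0.12). Of 10 interferon-stimulated genes, the antiviral genes Rsad2 (−1.09) and Ifit3 (−1.03) were lower and 8 within 2-fold, with a median of −0.56. Rsad2 and Ifit3 were the 2 genes at least 2-fold lower on all 3 stimulated arrays than on the untreated array. High levels on the untreated array alone would give the same pattern. The 26 NF-kappaB and inflammatory genes had a median of 0.00, with Il6 the 1 member at least 2-fold higher.

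Of the 79 higher genes, 15 were at least 2-fold above untreated on all 3 stimulated arrays, and 12 of these 15 had an untreated signal under the filter level. Psmc4, a proteasome subunit gene read as 5.59-fold higher, belonged to them, and its other probe set differed by 0.06. Klk7, Magea7-ps, Cep126 and 1810064F22Rik, also among the 15 largest increases, belonged to the same set. Of 28 higher genes with at least 2 probe sets, 22 had all of them on the same side, and the 40 other probe sets had a median of 0.38 with 10 at least 2-fold higher, while of 15 such lower genes 9 did, and the 24 others had a median of −0.30 with 6 at least 2-fold lower. The counts were 50 and 21 with the pseudocount at the median, 48 and 22 with the stricter filter, and 351 and 278 with no filter.

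**Figure D1:**
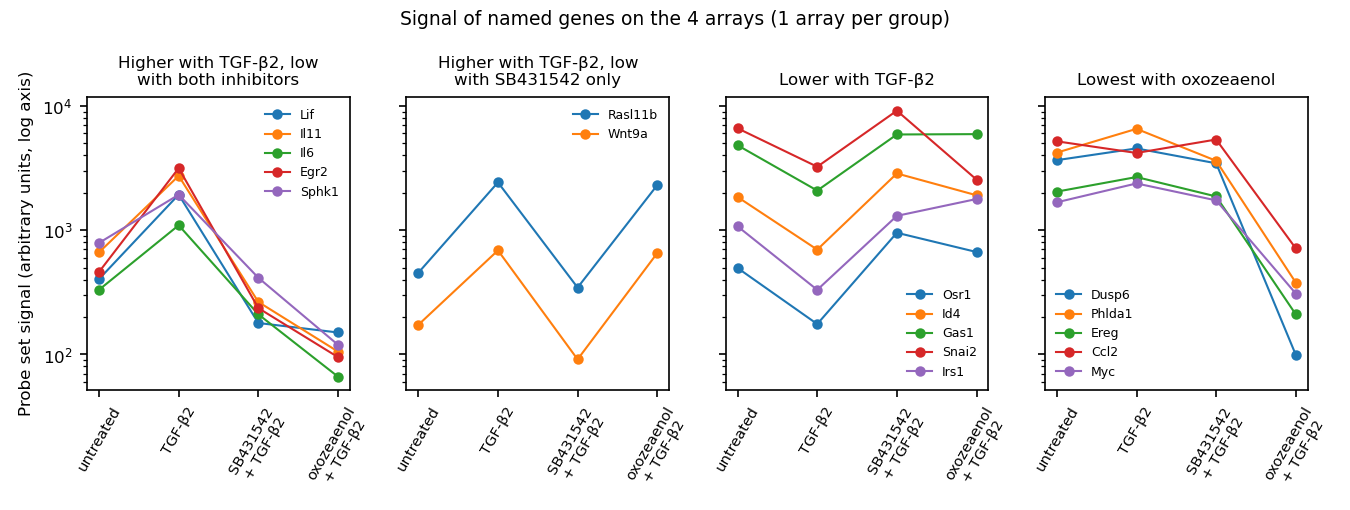
Deposited signals (log axis, arbitrary units) of named genes on the 4 arrays, 1 point per array, with lines joining the points of a gene. Lif, Il11, Il6, Egr2 and Sphk1 peak with TGF-beta2 alone, while Rasl11b and Wnt9a are low only on the untreated and SB431542 arrays.

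The next comparison asks which levels depend on the type I receptor kinase, by setting SB431542 with TGF-beta2 against TGF-beta2 alone. Transcripts that were at least 2-fold higher with TGF-beta2 over untreated were among the lowest with SB431542. Fgf21 read 57.2, under the filter level, against 1056. Egr2 was 12.3-fold lower, Lif 9.73-fold, Il11 9.64-fold and Has2 6.96-fold. Osr1 was 4.94-fold higher with the inhibitor, Id4 4.01-fold, and Irs1 3.76-fold. In all, 72 genes were at least 2-fold higher and 139 at least 2-fold lower.

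Of the 37 Smad targets, 10 were at least 2-fold lower with SB431542, 2 were higher and 25 were within 2-fold, with a median of −0.27 (random −0.05 to 0.09). The lower ones included the Smad feedback genes Skil (−1.41), Ldlrad4 (−1.39) and Pmepa1 (−1.13), and the higher ones were Snai2 (1.49) and Cited2 (1.01). The immediate early list had a median of −0.57, with Egr2, Junb, Egr3 and Ier5 at least 2-fold lower and 20 of 24 genes within 2-fold. For MAPK feedback genes the median was −0.25, and Dusp4 (−1.86), Dusp5 (−1.42) and Errfi1 (−1.17), an inhibitor of the EGF receptor, were lower. NF-kappaB and inflammatory genes had a median of −0.02, with Il6 (−2.27) and the prostaglandin synthase gene Ptgs2 (−1.24) lower and 24 within 2-fold. Of 11 BMP/Id targets, 4 were at least 2-fold higher, namely Id4, Atoh8, Hey1 and Id3, and the median was 0.58. Among palatal regulators, Osr1 (2.31), Bmp4 (1.37), Alx1 (1.15, with its probe sets again differing in direction) and Shox2 (1.01) were higher and Mn1 (−1.08), a transcriptional regulator needed for palate growth, was lower. The 9 measured Wnt targets had a median of −0.40, after 0.30 with TGF-beta2 alone over untreated, and Lef1 (−1.20) and Wnt11 (−1.04) were lower.

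Compared with the untreated culture, SB431542 with TGF-beta2 left 55 genes at least 2-fold higher and 45 lower, or 40 and 43 without genes that differed alike on all 3 stimulated arrays. The 17 other probe sets of the higher genes had a median of 0.16, with 0 at least 2-fold higher. Il11 (−1.26), Lif (−1.08) and Has2 (−1.63) lay below their untreated levels, and in all 27 of the 139 genes did so by at least 2-fold. Of 10 interferon-stimulated genes, Ifit3 (−1.47) and Rsad2 (−1.41) were at least 2-fold lower than untreated and 8 were within 2-fold, with a median of −0.78. Among the 79 genes higher with TGF-beta2, the median position with SB431542 was 0.116 (95% interval over genes −0.141 to 0.445), where 0 is the untreated level and 1 the level with TGF-beta2 alone. Genes picked by the same rule in simulated unchanged arrays had a median position of 0.517 (0.436 to 0.605). Of the 79, 45 had a position under 0.25 and 21 over 0.75. The 21 include most of the 15 genes higher on all 3 stimulated arrays. Over the alternatives the median position lay between −0.171, with the stricter filter, and 0.433, with no filter, and it was −0.126 without the 15 genes higher on all 3 stimulated arrays. For the 43 genes lower with TGF-beta2, the median position was 0.117. A single low reading on the TGF-beta2 array would also give a position near 0.

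The higher and lower counts with SB431542 became 31 and 86 with the pseudocount at the median, 37 and 90 with the stricter filter, and 463 and 405 with no filter. Against untreated they became 25 and 16, 14 and 12, and 457 and 258 in the same order, and 47 and 55 under quantile normalization, where lower genes outnumber higher ones.

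The Tak1 comparison sets oxozeaenol with TGF-beta2 against TGF-beta2 alone. Immediate early transcription factors and brakes on MAP kinase signalling were among the lowest transcripts. Egr1 was 53.2-fold lower, from 10257 to 171, Dusp6, a phosphatase of ERK, 37.8-fold lower, from 4547 to 99.3, and Egr2 27.2-fold lower. Il11 was 21.7-fold lower, and the growth factor gene Hbegf 16.3-fold. Among the highest were genes of stratified epithelium, including the keratin genes Krt13, from 24.3 to 2023, and Krt6b, from 56.0 to 3060, and the keratinocyte differentiation gene Krtdap, from 5.6 to 951. Their signals with TGF-beta2 alone lay under the filter level, so the size of these differences depends on the pseudocount. In all, 214 genes were at least 2-fold higher and 255 at least 2-fold lower.

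Of 24 immediate early genes, 17 were at least 2-fold lower with oxozeaenol and none higher, with a median of −1.30 (random −0.09 to 0.17). Fos (−2.86), Fosl1 (−2.90) and Myc (−2.86) were among them. Of 15 MAPK feedback genes, 9 were lower, including Phlda1 (−4.03) and Spred2 (−2.78), and the median was −1.42. Of 26 NF-kappaB and inflammatory genes, 11 were lower and none higher (median −0.68, random −0.09 to 0.18). These included the chemokines Ccl2 (−2.51) and Ccl7 (−2.01), Tnf, from 116 to 10.5, and Tnfaip3 (−1.84), a feedback inhibitor of NF-kappaB. Of the 37 Smad targets, 13 were lower, 1 was higher and 23 were within 2-fold (median −0.39). Il11, Hbegf, Sphk1, Lif, Bhlhe40 and Junb were lower, as were Smad7 (−1.03) and the chromatin protein gene Hmga2 (−2.13). Of 11 BMP/Id targets, Id4 (1.43), Hey1 (1.27) and Smad6 (1.14) were higher, Id1 (−1.15) was lower and 7 were within 2-fold, with a median of 0.35. Osr1 (1.80), Bmp4 (1.91), Alx1 (1.69) and Shox2 (1.24) were higher, as with SB431542, and Fgf7 (−1.19), a growth factor for epithelium, was lower.

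Many of these levels lay under those of the untreated culture. Against untreated, 175 genes were at least 2-fold higher and 177 lower, and 133 of the 255 genes were also at least 2-fold below untreated. The median against untreated was −0.91 for immediate early genes, −1.0 for MAPK feedback genes and −0.63 for NF-kappaB and inflammatory genes. On the SB431542 array the same medians were −0.14, −0.08 and −0.03. Extracellular matrix genes had a median of 0.02 against untreated with oxozeaenol, with Has2 (−1.95) the 1 of 26 at least 2-fold lower. The 8 macrophage and blood markers had a median of −0.29 against untreated (random −0.14 to 0.11). Csf1, the macrophage growth factor, had a signal of 3206 with oxozeaenol against 8316 untreated.

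**Figure D2:**
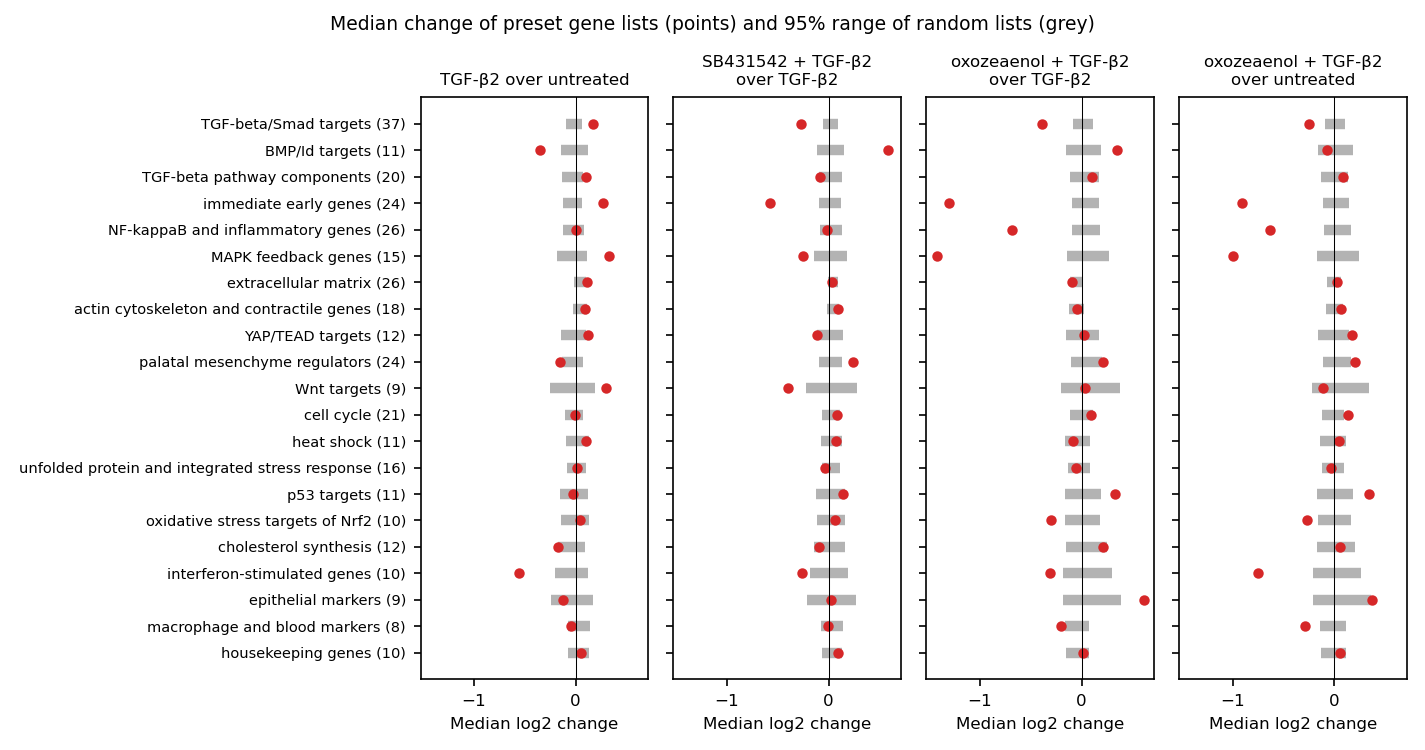
Median log2 change of the preset lists (red points, number of measured genes in brackets) and the range of 95% of expression-matched random lists (grey bars), for 4 comparisons. The endothelial, skeletal muscle and neural lists, with few measured genes, are left out. Immediate early, MAPK feedback and NF-kappaB genes have medians of −1.30, −1.42 and −0.68 with oxozeaenol over TGF-beta2 alone.

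Epithelial genes stood apart on the oxozeaenol array. Of 9 preset epithelial markers, Krt14 (2.82), Krt5 (2.46) and Krt19 (from 34.7 to 209), keratins of basal and simple epithelium, were at least 2-fold higher than with TGF-beta2 alone and 6 were within 2-fold (median 0.61, random −0.18 to 0.39). Cdh1, the epithelial cadherin, read 230 with TGF-beta2 and 463 with oxozeaenol. In the list written after the data had been seen, 23 of 24 suprabasal and cornified genes and 6 of 19 basal and adhesion genes were at least 2-fold higher. Leaving out this list and all other keratin, small proline-rich and late cornified envelope genes kept 11683 genes, of which 184 were higher and 255 lower. Outside epithelium, 3 of 11 p53 targets were higher, namely Trp53inp1 (1.92), Fas (1.38) and Sesn1 (1.31), and 1 lower, with a median of 0.33. The 10 targets of Nrf2, a regulator of antioxidant genes, were all within 2-fold with a median of −0.30, and Hmox1, heme oxygenase, read 9474 with TGF-beta2 and 5593 with oxozeaenol.

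Among the 79 genes higher with TGF-beta2, the median position with oxozeaenol was 0.341 (0.194 to 0.822), against 0.505 (0.423 to 0.574) in simulated unchanged arrays. Positions were split, with 33 genes under 0.25 and 33 over 0.75. The latter include most of the 15 genes higher on all 3 stimulated arrays, such as Psmc4, which may be low readings on the untreated array. Over the alternatives the median lay between −0.081, with the stricter filter, and 0.58, with the pseudocount at the 10th percentile, and it was 0.212 without the 15 genes higher on all 3 stimulated arrays. For the 43 genes lower with TGF-beta2, the median position was 0.113, against 0.117 with SB431542. A single low reading on the TGF-beta2 array would give positions near 0 with both inhibitors. The count of higher genes was 141 with the pseudocount at the median, 111 with the stricter filter and 587 with no filter, where 512 were lower. Against untreated the higher and lower counts were 79 and 132 with the stricter filter, 146 and 200 with median centring, and 564 and 359 with no filter.

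**Figure D3:**
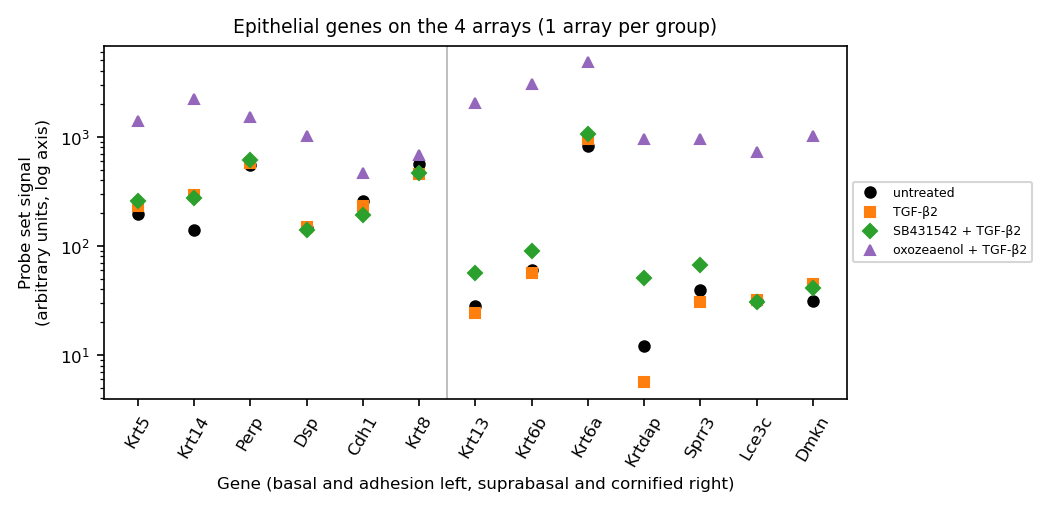
Deposited signals (log axis, arbitrary units) of selected epithelial genes, with 1 symbol per array. Krt13 reads 28.0 untreated, 24.3 with TGF-beta2, 55.8 with SB431542 and 2023 with oxozeaenol.

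The last comparison asks how the inhibitors differ. Of the 79 genes at least 2-fold higher with TGF-beta2, 42 (53.2%) were at least 2-fold lower with SB431542 than with TGF-beta2 alone, 33 (41.8%) with oxozeaenol and 29 (36.7%) with both, including Lif, Il11, Il6, Egr2, Sphk1 and Vegfa. Of 609 genes picked by the same rule over all simulated unchanged arrays, the shares were 7.9%, 9.2% and 2.5%. A reading too high on the TGF-beta2 array alone would also give lower values with both inhibitors. The simulated noise holds few such readings, so these shares do not settle how much of the difference is chance. Of the 43 lower genes, 29 were at least 2-fold higher with SB431542 and 24 with oxozeaenol, among them Osr1, Id4 and Irs1. A reading too low on the TGF-beta2 array alone would likewise give higher values with both inhibitors. No simulated share was computed for the lower genes, so how much of this is chance is not known. Rasl11b and Wnt9a, from the 79 higher genes, were exceptions to lower values with both inhibitors. Rasl11b read 2424 with TGF-beta2, 345 with SB431542 and 2302 with oxozeaenol, and Wnt9a read 687, 91.3 and 654 on the same arrays. In all, 12 of the 79 genes were lower with SB431542 and within 2-fold of TGF-beta2 alone with oxozeaenol. Gene by gene, the position with oxozeaenol minus that with SB431542 had a median of −0.038 (−0.154 to 0.124) over the 79, with 42 genes at or under 0 and the others above it. In simulated unchanged arrays this difference had a median of −0.037 (−0.119 to 0.079).

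Oxozeaenol over SB431542, both with TGF-beta2, gave 177 genes at least 2-fold higher and 153 lower. MAPK feedback genes had the lowest list median, −1.39, with 10 of 15 at least 2-fold lower and none higher. For Dusp6 the log2 change was −4.84, for Phlda1 −3.18 and for Ereg, an EGF receptor ligand, −3.03. Immediate early genes had a median of −0.88, with 11 of 24 lower, and NF-kappaB and inflammatory genes −0.26, with 8 of 26 lower. Smad targets had a median of −0.12 (random −0.09 to 0.08), with 6 of 37 lower, 2 higher and 29 within 2-fold. Snai2 (−1.83) and Id1 (−2.08) were lower with oxozeaenol. Ch25h, which makes an oxysterol, read 2939 with TGF-beta2, 2379 with SB431542 and 184 with oxozeaenol. Ahr read 1435 with SB431542 and 367 with oxozeaenol, against 410 with TGF-beta2 alone. Epithelial genes were among the highest, and Krt6b read 88.9 with SB431542 and 3060 with oxozeaenol. The balance of higher and lower genes turned with the setting, to 146 and 153 without those epithelial genes, 150 and 179 with median centring, 161 and 168 under quantile normalization, and 78 and 106 with the stricter filter. With the pseudocount at the median the counts were 110 and 113, and with no filter 527 and 473.

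**Figure D4:**
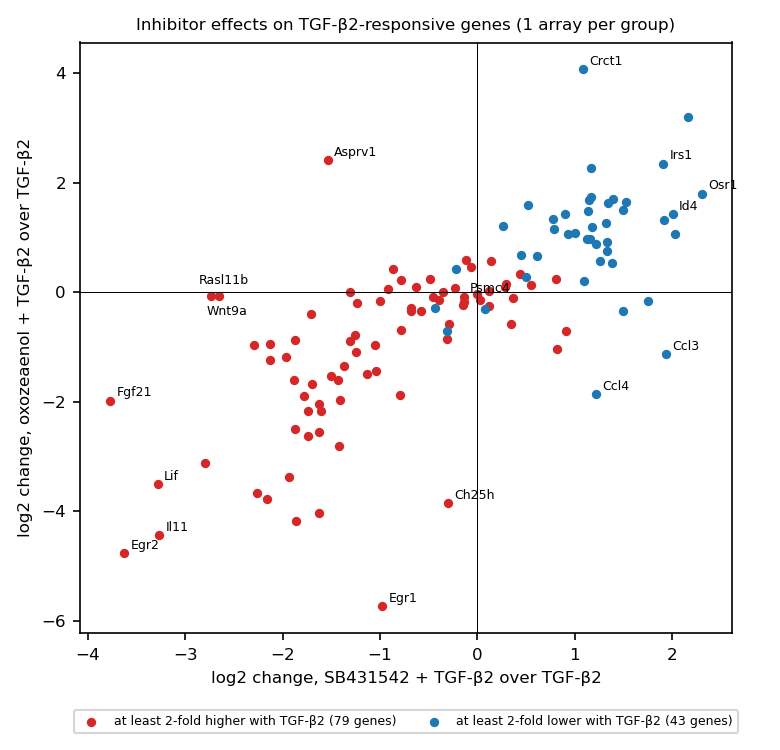
Log2 change with SB431542 (x axis) against that with oxozeaenol (y axis), each over TGF-beta2 alone, for the 79 genes at least 2-fold higher (red) and 43 at least 2-fold lower (blue) with TGF-beta2. Lif, Il11 and Egr2 lie at the lower left, and Rasl11b and Wnt9a lie near −0.07 on the y axis.

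Both inhibitor effects use the same TGF-beta2 array, so they share its chance values. Their correlation across genes was 0.517, against 0.499 in simulated unchanged arrays, and their covariance was 0.0873 against 0.0288. At least 2-fold lower with both inhibitors were 66 genes, against 1 in simulated unchanged arrays and 3.0 for independent lists of these sizes. For genes higher with both, the numbers were 34, 0 and 1.3. With 1 array per group the shared array could not be split, so part of the excess may come from it. The differences between inhibitors were not tested, and an inhibitor given without TGF-beta2 was not analysed here.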

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

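The tests of epithelial cell content and response, of probe sets, of dilution and of RNA quality were chosen after the results were seen, whereas the scaling alternatives were fixed before.

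Asprv1, Ccl3, Ccl4 and Lce3a were at least 2-fold apart from TGF-beta2 alone in opposite directions with the 2 inhibitors, which drew attention to them, although the difference was not tested. The log2 change of oxozeaenol over SB431542 was 3.95 for Asprv1, a protease gene of differentiated epidermis, and 4.16 for Lce3a, a cornified envelope gene. Their signals with SB431542, 15.8 and 12.9, lie under the filter level and the pseudocount, so the sizes, and whether either is at least 2-fold lower with SB431542, depend on the pseudocount. The change was −3.06 for Ccl3 and −3.08 for Ccl4, both macrophage chemokines. Each of these genes has 1 kept probe set. Among the 1886 kept probe sets with no listed gene, 18 were at least 2-fold higher with TGF-beta2 than untreated, and 18 were at least 2-fold higher with oxozeaenol than with TGF-beta2 alone. The control probe set for the Bacillus dap transcript was 1.71 times as bright on the TGF-beta2 array as on the untreated array, at 1342 against 784, with 998 for SB431542 and 1341 for oxozeaenol, so the untreated array was the lowest.

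Epithelial genes, chiefly those of the suprabasal and cornified class, were higher on the oxozeaenol array. Of 19 basal and adhesion genes, 6 were at least 2-fold higher than with TGF-beta2 alone. Scaling between the arrays is argued against, since the median log2 change of the suprabasal and cornified genes over the SB431542 array was at least 3.19 under each of 3 scalings. That class was listed after its genes were seen to be high there, so the value speaks to scaling alone. More epithelial cells in that culture would be expected to raise most basal and adhesion genes, and 57.9% of those measured were highest there. That share lies between the bounds set for and against it. The bounds and this class were also written after the data had been seen. Krt5, Krt14 and Dsp were higher than with TGF-beta2 alone by log2 changes of 2.46, 2.82 and 2.60. Dsp encodes desmoplakin and was named after its values were seen. Epcam, at 0.61, was within 2-fold. On the untreated array 19 of 19 basal and adhesion genes and 11 of 24 suprabasal genes were above the filter level. These genes were kept because their mean over the arrays reached that level, so this says little about which cells were present. A response of epithelial cells present in every culture also stays open. On all 3 other arrays 16 basal and adhesion genes were above the filter level, which is likewise largely set by the filter. With 1 culture per treatment these explanations cannot be told apart.

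Another pattern is the set of 15 genes that were at least 2-fold higher on all 3 stimulated arrays than on the untreated array. Scaling is argued against, since at least 13 of them kept this under each of 3 scalings. Low readings of single probe sets on the untreated array and a TGF-beta2 response that neither inhibitor blocked cannot be told apart for most of them, because only 3 genes have a second kept probe set. Those probe sets differed by a median of 0.02 with TGF-beta2, which for Psmc4, Slc4a8 and Zxdb (the last 2 named after their values were seen) argues against a response of the whole gene. By contrast, 29 further probe sets of the 42 genes that were higher with TGF-beta2 and lower with SB431542 had a median of 0.69.

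The third pattern is that immediate early, MAPK feedback and inflammatory genes lay below their untreated level with oxozeaenol, 57 of 65 of them, with a median of −0.86. By the 2-fold rule, 29 of the 65 were lower. Scaling is argued against, since the median was at most −0.86 under each of 3 scalings. Dilution by RNA of another cell type is argued against by the extracellular matrix genes, whose median against untreated was 0.02, but the 8 macrophage and blood markers had a median of −0.29 (random −0.14 to 0.11), so fewer macrophages may account for part of the lower inflammatory genes. Degraded RNA is argued against by the actin 3′ to 5′ signal ratio, which was 0.997 times the highest of the other arrays. A candidate explanation that stays open is loss of kinase signalling that is also active without added TGF-beta2, through Tak1 or another target of oxozeaenol. These arrays do not separate the targets. Every array with an inhibitor also had TGF-beta2, so this loss cannot be told apart from an effect on the response to TGF-beta2.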

How the results depend on the processing

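The alternatives that leave out epithelial genes, leave out genes shared by all 3 stimulated arrays, or require probe sets to share a direction were chosen after the data were seen. Of 184 counts, positions and preset list medians recomputed, 160 stayed close and 24 did not, and the latter came from the filter and pseudocount except where given below. Of 12228 recomputed single gene changes, 12131 stayed close, 96 moved and 1 reversed, and of 974 other list medians, 943 stayed close, 30 moved and 1 reversed. These totals overstate the agreement. Removing or tightening the filter, or leaving genes out, cannot alter the change of a gene that remains. For example, all 336 named calls measured with no filter were still at least 2-fold. Many counts and list medians are likewise fixed when genes are left out. Close means within 1.5 times for a count or single gene, and for a median a shift below the half-width of its interval or random range. Reversed means a change of sign in a gene at least 2-fold apart or a list median outside its random range, so sign changes of medians inside that range are not counted. By this rule the median position with SB431542 counts as close at −0.171 with the stricter filter, although it changed sign and lies outside its interval.

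For TGF-beta2 over untreated, SB431542 over TGF-beta2, oxozeaenol over TGF-beta2 and oxozeaenol over SB431542, in that order, the numbers of higher genes were 351, 463, 587 and 527 with no filter, and of lower genes 278, 405, 512 and 473. More genes enter without the filter, and they are dim. With the stricter filter the higher genes numbered 48, 37, 111 and 78, and the lower genes of the first pair of comparisons 22 and 90. With the pseudocount at the median the higher genes numbered 50, 31, 141 and 110, and the lower genes of the first pair 21 and 86. The median position with SB431542 was 0.433 with no filter, and that with oxozeaenol −0.081 with the stricter filter. The Smad target median with TGF-beta2 was 0.101 under quantile normalization, and the NF-kappaB median with oxozeaenol −0.543 with the mean of probe sets. The YAP/TEAD median with SB431542 turned from −0.11 to 0.01 with the mean of probe sets, and Dus2 with oxozeaenol from 1.74 to −0.58 without probe sets ending in _x_at or _s_at, where another probe set stands for the gene. For the values not settled by construction, the cause was not tested.

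Quantile normalization, median centring and cyclic loess kept each of these counts within 1.5 times, and 76 of the 79 genes higher with TGF-beta2 remained under quantile normalization. No paired analysis was possible because each group has 1 array. For the same reason no array could be left out. Dim probe sets, whose log2 values depend on the pseudocount, limit what can be counted.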

Other observations

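The extra values below were chosen for description after the data were seen, and no explanation for them was tested.

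Of 12 macrophage and blood markers, 8 were measured past the filter in these mesenchymal cultures. Adgre1, which encodes the macrophage surface protein F4/80, read 4183 untreated, 3667 with TGF-beta2, 3434 with SB431542 and 3168 with oxozeaenol. Cd68 read 8687, 7443, 7858 and 6963 on the same arrays. Fcer1g, an immune receptor adaptor, read 9142 untreated and 6723 with oxozeaenol, and Ptprc, the leukocyte phosphatase, 1721 and 1139. All 8 measured members of the macrophage and blood list were within 2-fold in every comparison, with median log2 changes of −0.05 for TGF-beta2 over untreated and −0.20 for oxozeaenol over TGF-beta2. Ccl3 and Ccl4 are chemokines that macrophages make, and their signals are thus not assigned to a cell type here.

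Of 10 interferon-stimulated genes, 2 with TGF-beta2, 2 with SB431542 and 4 with oxozeaenol were at least 2-fold lower than untreated, and none was higher. Rsad2, an antiviral enzyme, read 2730 untreated, 1268 with TGF-beta2, 1016 with SB431542 and 770 with oxozeaenol. Ifit3 read 965, 460, 335 and 376 on the same arrays. The list of 10 genes had medians against untreated of −0.56 with TGF-beta2, −0.78 with SB431542 and −0.75 with oxozeaenol.

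The 21 cell cycle genes were all within 2-fold in each comparison, with a median of 0.09 for oxozeaenol over TGF-beta2. The 18 actin and contractile genes had a median of 0.09 with TGF-beta2, which was −0.008 under quantile normalization, and with oxozeaenol over TGF-beta2 Lmod1 (1.21) was at least 2-fold higher, Zyx (−1.09) and Itga5 (−1.01), both of focal adhesions, were lower and 15 were within 2-fold. Heat shock genes had medians of 0.10 with TGF-beta2 and −0.08 with oxozeaenol, where Hspa1a (1.31) was higher and the co-chaperone gene Bag3 (−1.12) lower. Stress response genes had medians of 0.01 and −0.05 in the same comparisons, and cholesterol synthesis genes −0.17 and 0.21. For the 12 YAP/TEAD targets the medians were 0.12 and 0.02. Lats2 (1.05) was higher with TGF-beta2, and Ccn1 (−1.41), F3 (−1.26) and Ankrd1 (−1.05) were lower with oxozeaenol, with 9 within 2-fold. The stress response median of 0.01 and the YAP/TEAD median of 0.02 turned below 0 under at least 1 scaling. The endothelial, skeletal muscle and neural lists, with 4, 4 and 5 measured genes, had medians of −0.16, 0.09 and 0.01 with TGF-beta2.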
